A study of Mus musculus with 12 samples.

How the data were processed

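The data were 12 sequencing libraries from mouse skin, per the labels: 3 control samples and 3 UV-exposed samples, each with an antibody-enriched (IP) library for N6-methyladenosine (m6A) and an input library made from total RNA with a stranded mRNA kit. The type, dose and timing of UV, the antibody and the time of day of collection are not given in the sources used here. Nothing in the labels says whether the samples within a condition are separate animals, so each p-value measures the spread between these samples.

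The deposited count table held raw read counts per gene for all 12 libraries over 49492 genes. The submitters' processing notes name STAR 2.5.3a and the GRCm38 genome build. The read counter, the annotation release, the use of strand and the handling of duplicates are not given in the sources used here. Between 79.5% and 83.6% of the counts from 1 to 20 in each library were even numbers, a pattern that arises when both mates of a pair are counted as separate reads. The deposited peak table held raw read counts per peak and library, with peaks given as called in the UV arm or in the control arm. Per the file headers it also held a log2 fold change of enrichment between UV and control computed by the authors, with the authors' p-value and FDR for each peak. Recomputing the Benjamini-Hochberg adjustment from the authors' p-values gave the deposited FDR. The peak caller and the authors' test are not given in the sources used here. Peak starts in the deposited file counted from 0: 1966 starts met an annotated exon start after 1 was added, against at most 118 at the other offsets tried. Peak coordinates are printed counting from 1.

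Gene symbols were those of the deposited table. Of its 49492 genes, 35438 matched a current RefSeq symbol, among them 956 through an older symbol. Virma (KIAA1429) was held under an older symbol. RefSeq was also used for gene classes.

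Reads in genes ranged from 24126662 to 92163619 per library. Counts were normalised with TMM and filtered with filterByExpr, then tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. A gene or peak was called at a Benjamini-Hochberg adjusted p below 0.05. Expression was compared between the 3 UV and 3 control input libraries, and IP abundance between the 3 UV and 3 control IP libraries. m6A enrichment was fitted on all 12 libraries with 4 group means: IP against input within control, IP against input within UV, and the interaction, which is the change of IP over input between UV and control. The same interaction was tested for each of 42989 peaks. The 5 gene-level comparisons were each adjusted over all genes tested. Abundance is given as CPM, counts scaled to library size with TMM factors. Values are means ± SD over replicates or log2 changes with their standard error (SE).

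The sample numbers were checked by correlating the departures of libraries from their group means over 12596 genes. IP and input of the same sample number correlated at 0.591 to 0.856 and IP and input of different numbers at −0.688 to −0.16, so the numbers pair IP with input. A fit with the sample as a block shared by IP and input (sample block) is given beside the enrichment comparisons where it changes a call or a count by more than 1.5 times. The same number in control and UV did not pair samples: the correlations were −0.096, 0.11 and −0.251 for input. The spread between replicates exceeded counting noise, with a chi-square per degree of freedom of 62.4 to 221 in every pair of replicates.

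A total of 33 gene lists were tested for expression and for the enrichment interaction with camera of limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2), then with an estimated correlation and with fry. The lists covered m6A machinery, interstitial collagens, collagen-processing enzymes, elastic fibres and microfibrils, small leucine-rich and large proteoglycans, basement membrane, matrix metalloproteinases and their inhibitors, TGF-beta signalling, stress keratins, basal and differentiated keratinocytes, hair, sebocytes, adipocytes, skeletal muscle, fibroblasts, macrophages, neutrophils, T cells, mast cells, Langerhans and dendritic cells, endothelium, smooth muscle, melanocytes, Schwann cells, erythroid cells, cytokines, interferon response, the p53 response, senescence, antioxidant genes, cell cycle and immediate early genes. Krt85 of the hair list was not in the table. A further 5 lists (clock output, clock activators, gamma delta T cells, alpha beta T cells, MHC class II) were written after the expression values had been seen. Ribosomal protein genes, whose transcripts carry little m6A, were compared with all genes in each IP and input pair.

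Genes were named by a fixed rule. Virma and Mfap4 came first. Then came up to 10 called genes per direction with the largest change, a mean of at least 5 CPM and replicates of the 2 groups that did not overlap, leaving out Gm and Rik names. Up to 4 members per list with the smallest p, the peaks of Virma, Mfap4 and the interstitial collagens, 10 peaks per direction with the smallest p, and the 5 most enriched and 5 most depleted called genes with at least 5 CPM in input within each group completed the rule. The comparisons, tests, lists, naming rule and most alternatives were set before the data were examined.

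The alternatives were size factors of DESeq2 1.42.0, library size alone, the DESeq2 Wald test, no low-count filter, a filter of 1 CPM, limma-voom, an added requirement of a 2-fold change, the blocks, counts divided by 2, each arm's peaks alone, a shared-peak definition of 50% of the shorter peak, and leaving out each sample in turn. Overlaps were computed with bedtools 2.31.1. Scaling by library size alone moved the median log2 change of all genes from −0.02 to −0.12 for expression, from −0.04 to −0.29 for enrichment in control, from −0.01 to −0.16 for enrichment in UV and from 0.00 to 0.09 for the interaction, so all changes are relative to the TMM average gene.

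The tests were tested on simulated counts with 100 genes or peaks changed 2-fold and 100 changed 4-fold. For expression (23766 genes simulated) 71% of 2-fold and 98% of 4-fold changes were recovered, and 7.14% of calls were false. For IP abundance (22329 genes) 79% and 99% were recovered with 4.30% false. For the interaction (24611 genes) 49% and 91% were recovered with 4.76% false, and with the sample block (24665 genes) 43% and 88% with 10.3% false. For peaks (39515) 40% and 93% were recovered with 5% false, and with the sample block (39535) 35% and 90% with 11.4% false. In these simulations the blocked fits called somewhat more false positives than their threshold states. The unblocked interaction and peak simulations drew IP and input of a sample independently, unlike the data. The blocked ones added a sample effect to dispersions that already held the spread between samples. The rates of both may therefore differ in the real data. In the simulated list test the 20-member changed list was found and 0 of 33 random lists were called. Genes were simulated independently there, whereas the estimated correlation in the real lists reached 0.97 (hair list, expression). The simulation therefore cannot show how camera with the preset correlation behaves on correlated lists.

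Raw reads and a reference genome were not used here, so alignment, peak calling, strand and duplicates were not analysed here. Intervals and floors for low counts cover counting error only.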

Results

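Skin of control and UV-exposed mice was profiled by m6A RNA immunoprecipitation and sequencing, with 3 samples per condition and an IP and an input library from each. The series is about the m6A writer subunit KIAA1429 (Virma), the microfibril protein gene Mfap4 and collagen synthesis in photoaged skin. Reads in genes numbered 58015420, 24126662 and 59732603 in the control input libraries 1 to 3 and 36834233, 50264113 and 67060422 in the UV input libraries. The control IP libraries held 58756881, 57621467 and 27685764 reads in genes and the UV IP libraries 34339480, 92163619 and 44655078. The 10 most abundant genes took 20.7% to 27.0% of the reads of a library.

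The first question was whether Virma and Mfap4 differ between UV and control skin. Virma, a scaffold subunit of the m6A methyltransferase complex on chromosome 4 (11485958 to 11550684, GRCm38), had 82.5, 98.7 and 90.3 CPM in the control input libraries and 103.5, 114.7 and 114.3 CPM in the UV ones. Its log2 change was 0.29 (SE 0.09, adjusted p = 0.0937, n = 3 per group) and was not called, although every UV value lay above every control value. The DESeq2 Wald test called it (0.31, adjusted p = 0.0399), within a range of adjusted p from 0.0399 to 0.304 over the alternatives. Mfap4, which encodes a glycoprotein of elastic microfibrils, lies on chromosome 11 (61485431 to 61488900) and had 17.5, 14.5 and 13.3 CPM in control against 8.04, 7.88 and 12.1 CPM in UV. Its log2 change of −0.69 (SE 0.18, adjusted p = 0.0634) was not called over all genes, while adjusted over the list alone, among elastic fibre genes, its p was 0.0148. Mfap4 was called with library size only (−0.81, adjusted p = 0.0328), with the DESeq2 Wald test (−0.68, adjusted p = 0.0114), without a low-count filter (adjusted p = 0.0235) and without UV replicate 3 (−0.92, adjusted p = 0.0371), within a range of 0.0114 to 0.21.

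Transcripts of Virma were enriched in the IP libraries in both groups, by a log2 IP over input of 0.79 (SE 0.08, adjusted p = 5.08e-06) in control and 0.54 (SE 0.08, adjusted p = 0.000112) in UV. The change between the groups was −0.24 (SE 0.11, unadjusted p = 0.0546, adjusted p = 1.00), and −0.25 (SE 0.08, adjusted p = 0.151) with the sample block. Mfap4 transcripts were near the average gene in both groups, with −0.28 (SE 0.21, adjusted p = 0.306) in control and 0.08 (SE 0.22, adjusted p = 0.796) in UV. With library size only the Mfap4 value in UV turned negative (−0.08, adjusted p = 0.785). In control, Mfap4 was called depleted with library size only (−0.53, adjusted p = 0.05) and with the sample block (−0.28, adjusted p = 0.0053). The change of Mfap4 between the groups was 0.35 (SE 0.30, adjusted p = 1.00), and 0.37 (SE 0.12, adjusted p = 0.146) with the sample block. The 3 UV samples had log2 IP over input values for Mfap4 of −0.07, 0.21 and 0.09, all above the control values of −0.23, −0.26 and −0.38.

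The expression comparison asked which transcripts differ between UV and control skin. Krt77, which encodes a keratin of the upper epidermis (chromosome 15, 101858732 to 101869705), fell from 3489 ± 712 to 262 ± 108 CPM (log2 change −3.73, SE 0.30, adjusted p = 0.00208, n = 3 per group). Dab1, which encodes a reelin adaptor (chromosome 4, 103619359 to 104744844), fell from 20.9 ± 5.41 to 1.42 ± 0.59 CPM (−3.93, SE 0.30, adjusted p = 0.00158). Fcgbp, which encodes a mucin-like secreted protein, fell from 207 ± 50.5 to 38.9 ± 8.12 CPM (−2.41, adjusted p = 0.00262). Dbp, a clock-controlled transcription factor gene (chromosome 7, 45705088 to 45710203), rose from 15.1 ± 2.29 to 55.8 ± 10.7 CPM (1.89, SE 0.16, adjusted p = 0.00229), and Fgfbp3, which encodes a fibroblast growth factor binding protein, rose from 1.94 ± 0.41 to 8.54 ± 3.56 CPM (2.10, SE 0.33, adjusted p = 0.0136).

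The other named genes that rose were the adhesion molecule gene Igsf9b (1.83), the ERBB ligand gene Nrg1 (1.83), the glutathione transferase gene Gsto1 (1.82), the carboxylesterase genes Ces2f (1.74) and Ces2g (1.66), the serine protease inhibitor gene Serpinb6c (1.67), Aadacl3 (1.64) and the receptor phosphatase gene Ptprz1 (1.58). The others that fell were the noncoding AY036118 (−3.95, from 72.2 ± 52.3 to 4.64 ± 0.45 CPM), the pseudogene Mrgprb9-ps (−3.32), the fast-muscle genes Pvalb (−2.18) and Actn3 (−1.89), the cadherin gene Cdh4 (−2.15), the ion exchanger gene Slc24a3 (−1.97) and the snoRNA gene Snord49a (−1.93). The values of AY036118, which overlaps a ribosomal RNA-like locus, and of the neighbouring paralogs Ces2f and Ces2g are uncertain because reads can be shared between similar sequences. AY036118 in control included a control replicate 2 value of 130.5 CPM, and without that sample its log2 change was −3.21. Pvalb in control, 51.3 ± 33.7 CPM, included a control replicate 2 value of 90.2 CPM, and without that sample its log2 change was −1.51. Leaving out single samples ended the calls of Fgfbp3 (adjusted p up to 0.0583, without Control 1, UV 1 or UV 2), Gsto1 (up to 0.0563, without Control 1 or UV 1) and Nrg1 (up to 0.0842, without Control 1, UV 1 or UV 2). The calls of Serpinb6c (up to 0.102), Ces2g (up to 0.13), Aadacl3 (up to 0.0792), Ptprz1 (up to 0.107) and Pvalb (up to 0.0986) ended without Control 1 or any of the UV samples, and that of Actn3 (up to 0.117) without any of these or Control 2.

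Over 24099 genes tested, 1404 were called, 728 higher and 676 lower in UV, of which 512 changed at least 2-fold (178 higher and 334 lower). With library size only, 455 were higher and 1019 lower, so that 30.9% of calls were higher against 51.9% with TMM. The number of calls was 219 without UV 1, 319 without UV 2, 336 without UV 3, 446 without Control 1, 1244 without Control 2 and 2100 without Control 3.

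**Figure D1:**
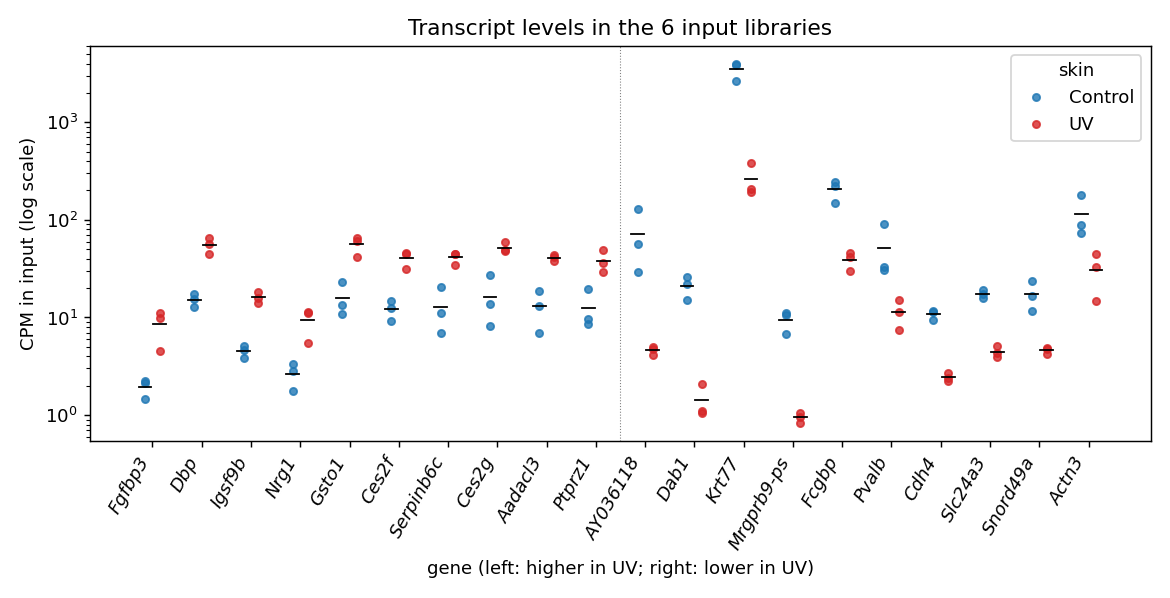
CPM on a log axis in each input library for the 20 named genes, with control in blue, UV in red and a black line at each group mean. The 3 UV libraries lie below the 3 control libraries for Krt77 and Dab1 and above them for Dbp.

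Gene lists asked which skin programmes moved, beginning with the DNA damage response and the dermal matrix. Among p53 and DNA damage response genes, the polymerase gene Polk (log2 change 1.29, SE 0.09, adjusted p = 0.00111), the receptor gene Eda2r (1.46, SE 0.14, adjusted p = 0.0035), the kinase gene Plk2 (0.84, adjusted p = 0.00468) and Ei24 (0.72, adjusted p = 0.00491) rose. Of the 21 measured genes of that list, 12 rose and 0 fell over all genes. Adjusted over the list alone 16 rose and 1 fell, with a list median of 0.43 (camera adjusted p = 5.14e-09, or 0.277 with an estimated correlation). The 12 became 8 with library size only or without Control 1, 7 without UV 2, 6 without UV 1 and 5 without UV 3. Cdkn1a (adjusted p up to 0.103), Aen (up to 0.11), Tnfrsf10b (up to 0.122) and Bax (up to 0.137) lost their calls in each of these, and Mdm2 (up to 0.0755) without any single UV sample. Zmat3 (up to 0.064) lost its call without UV 1 or UV 3, Trp53inp1 without UV 3 (0.051) and Bax also without Control 2 (0.0652). The collagen genes Col12a1 (0.71, adjusted p = 0.00967) and Col6a5 (0.87, adjusted p = 0.0153) rose, whereas Col15a1 (−0.51, adjusted p = 0.0177) and Col16a1 (−0.53, adjusted p = 0.0271) fell. Col1a2, which encodes a chain of type I collagen, fell by 0.50 (SE 0.12, adjusted p = 0.0487), a call that ended in 6 alternatives besides the 2-fold requirement, with an adjusted p of up to 0.194 without UV replicate 1. Calls also ended for Col15a1 (adjusted p up to 0.0974), Col16a1 (up to 0.126) and Col5a3 (up to 0.117) without Control 1 or any single UV sample, and for Col6a5 (up to 0.0745) without any single UV sample. Col1a1, at −0.53 (SE 0.13, adjusted p = 0.0508), was not called, although 5 alternatives called it (adjusted p from 0.000776 to 0.205 over all of them). Of 16 interstitial collagen genes 2 rose and 4 fell, and 2 rose and 8 fell adjusted over the list alone, with a median of −0.31 (camera adjusted p = 0.0283; adjusted p = 0.624 with an estimated correlation). The 4 lower genes became 0 without Control 1 or any single UV sample and 6 without Control 2.

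Among collagen-processing genes, the propeptidase gene Adamts14 (−1.13, adjusted p = 0.00812), the lysyl oxidase-like gene Loxl2 (−0.66, adjusted p = 0.0169), the enhancer gene Pcolce (−0.47, adjusted p = 0.0235) and the lysyl hydroxylase gene Plod1 (−0.45, adjusted p = 0.0256) fell. Of 27 members 0 rose and 6 fell, and 1 rose and 10 fell adjusted over the list alone, with a median of −0.28 (camera adjusted p = 0.0081; adjusted p = 0.624 with an estimated correlation). Among elastic fibre genes, Ltbp2 (1.10, adjusted p = 0.0074) rose, and Mfap2 (−0.82, adjusted p = 0.0107), Ltbp4 (−0.54, adjusted p = 0.0133) and Ltbp1 (−0.42, adjusted p = 0.0489) fell. Of 18 members 1 rose and 3 fell, and 1 rose and 5 fell adjusted over the list alone, with a median of −0.32 (camera adjusted p = 0.0206; adjusted p = 0.565 with an estimated correlation). The camera calls of these matrix lists ended when single samples were left out. For interstitial collagens this held for Control 1, Control 3, UV 1 and UV 3 (adjusted p up to 0.0819), for collagen-processing genes for Control 3 (0.0965) and for elastic fibres for Control 3, UV 1 and UV 3 (up to 0.0951). Single gene calls ended as well. Those of Pcolce (adjusted p up to 0.118) and Plod1 (up to 0.117) ended without Control 1 or any single UV sample. That of P4ha1 (up to 0.156) ended when any of the 6 samples was left out, and that of Pcolce2 (up to 0.141) without any single control sample, UV 1 or UV 2. Those of Loxl2 (up to 0.061) and Ltbp4 (up to 0.0765) ended without Control 1, UV 1 or UV 2. Ltbp1 (up to 0.19) lost its call without Control 1, Control 3 or any single UV sample, Mfap2 (up to 0.0582) without UV 1 or UV 3, and Adamts14 without UV 1 (0.0506). The lower genes numbered 0 of either list without UV 1 and 1 of either without Control 1 or UV 2.

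The proteoglycan genes Dcn (−0.77, adjusted p = 0.0133), Lum (−0.63, adjusted p = 0.0279) and Aspn (−0.68, adjusted p = 0.0487) fell, and the same 3 of 10 were called adjusted over the list alone, while the list was not called (camera adjusted p = 0.177). The perlecan gene Hspg2 (−0.43) was the 1 of 15 basement membrane genes called on either adjustment (camera adjusted p = 0.944; median −0.05, mean 0.02). Of 14 metalloproteinase and inhibitor genes, Timp4 (0.97) rose and Mmp14 (−0.53) and Mmp3 (−0.46) fell, with the same counts adjusted over the list alone. That list's median of −0.07 and mean of 0.11 differed in sign (camera adjusted p = 0.991). Tgfb2 (−0.59) was the 1 of 16 TGF-beta signalling genes called on either adjustment (camera adjusted p = 0.656). The calls of Lum (adjusted p up to 0.0944), Hspg2 (up to 0.121), Timp4 (up to 0.142) and Mmp14 (up to 0.0978) ended without Control 1 or any single UV sample. Those of Mmp3 (up to 0.159) and Tgfb2 (up to 0.152) ended without any of these. Mmp3 also lost its call without Control 3 and Tgfb2 without Control 2. The call of Aspn (up to 0.175) ended without any single control sample, UV 1 or UV 2, and that of Dcn (up to 0.071) without UV 1 or UV 3.

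Among genes of gland and fat cells, the lipid enzyme genes Far2 (0.82, adjusted p = 0.00423), Dgat2l6 (1.28, adjusted p = 0.00491) and Soat1 (0.96, adjusted p = 0.00587) rose. Of 10 sebocyte genes 6 rose and 0 fell, and 7 rose and 1 fell adjusted over the list alone, with a median of 0.70 (camera adjusted p = 0.000588; adjusted p = 0.565 with an estimated correlation). The 6 became 3 without Control 1, UV 1 or UV 2 and 4 without UV 3. Cidea (adjusted p up to 0.0738) lost its call in the first 3 of these, Elovl3 (up to 0.111) in all 4, and Cyp4f39 (up to 0.172) in all 4 and without Control 2. The lipid droplet gene Plin4 (0.81, adjusted p = 0.00686) and the adipogenic regulator gene Pparg (0.79, adjusted p = 0.0164) rose. The call of Pparg ended without Control 1, UV 1 or UV 2 (adjusted p up to 0.074). Of 14 adipocyte genes 4 rose and 0 fell, and 8 rose and 1 fell adjusted over the list alone, with a median of 0.32 (camera adjusted p = 0.00126; adjusted p = 0.565 with an estimated correlation). The 4 became 1 without Control 1, UV 1 or UV 2 and 2 without UV 3. Cidec (adjusted p up to 0.102) lost its call in each of these, and Cfd (up to 0.169) in these and without Control 2. Genes of skeletal muscle, which lies beneath the skin, had a median of −1.03, with 0 of 16 higher and 2 lower (Pvalb and Actn3), and 6 lower adjusted over the list alone (camera adjusted p = 0.000798; adjusted p = 0.646 with an estimated correlation). The 2 became 0 without Control 1 or any single UV sample. Of 25 hair shaft and root sheath genes 0 were called on either adjustment (4 fell without Control 3), with a median of −0.56 (camera adjusted p = 0.00776; adjusted p = 0.723 with an estimated correlation). The hair list was not called without Control 2 (adjusted p = 0.14) or UV 1 (0.278).

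In the epidermis, the integrin gene Itgb4 (1.04, adjusted p = 0.00863) rose and Krt15 (−0.72, adjusted p = 0.0361) fell. The call of Krt15 ended without Control 1, Control 2 or any single UV sample (adjusted p up to 0.142). Of 8 basal keratinocyte genes Itgb4 and Krt15 were the ones called over all genes, against 4 higher and 1 lower adjusted over the list alone (median 0.36; camera adjusted p = 0.0474; adjusted p = 0.617 with an estimated correlation). The transglutaminase gene Tgm3 (1.24, adjusted p = 0.00478) rose and Flg2 (−1.35, adjusted p = 0.00491), which encodes a filaggrin-related barrier protein, fell. The list of 20 differentiation genes, with 3 higher and 1 lower adjusted over the list alone, was not called (camera adjusted p = 0.0523). The stress keratin genes Krt6a (2.11, SE 0.76, adjusted p = 0.132), whose reads can be shared with Krt6b, and Krt16 (1.98, SE 0.92, adjusted p = 0.224) were not called. The 11-gene stress keratin list, with 0 genes called on either adjustment, had a median of 0.67 (camera adjusted p = 0.0165; adjusted p = 0.646 with an estimated correlation). Without Control 3, 6 stress keratin, 3 basal keratinocyte and 4 differentiation genes rose over all genes. Leaving out Control 1, Control 2, UV 1 or UV 2 ended the basal keratinocyte call (adjusted p up to 0.112), and leaving out Control 2, UV 1 or UV 2 ended the stress keratin call (up to 0.0629).

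Among immune genes, the T cell receptor complex genes Cd3g (−2.79, SE 0.18, adjusted p = 0.00111) and Cd3e (−3.01, SE 0.25, adjusted p = 0.00229) and the delta chain gene Trdc (−2.92, SE 0.47, adjusted p = 0.0142) fell. Of 11 T cell genes 0 rose and 3 fell, and 5 fell adjusted over the list alone (median −0.33; camera adjusted p = 0.00776; adjusted p = 0.565 with an estimated correlation). The T cell list was not called without UV 3 (adjusted p = 0.0735), and Trdc was not called without UV 2 (0.0663) or UV 3 (0.065). The Langerhans cell gene Cd207 (−1.60, SE 0.21, adjusted p = 0.0074) and the antigen presentation genes Cd74 (−0.84, adjusted p = 0.00573), H2-Ab1 (−0.54, adjusted p = 0.0225) and H2-Aa (−0.66, adjusted p = 0.0278) fell. The calls of H2-Ab1 (adjusted p up to 0.0841) and H2-Aa (up to 0.0954) ended without Control 1 or any single UV sample, and that of H2-Eb1 (up to 0.13) without any of these or Control 2. Of 7 Langerhans and dendritic cell genes 5 fell on either adjustment, and 2 without Control 1 or any single UV sample (median −0.54; camera adjusted p = 0.00251; adjusted p = 0.565 with an estimated correlation). The mast cell protease genes Mcpt4 (0.71, adjusted p = 0.0655) and Cpa3 (0.85, adjusted p = 0.0682) were not called over all genes, and 5 of 7 mast cell genes were higher adjusted over the list alone (median 0.84; camera adjusted p = 0.00516; adjusted p = 0.565 with an estimated correlation). Lyz2 (−0.51) and Csf1r (−0.63) fell among 13 macrophage genes, and were the 2 called adjusted over the list alone (camera adjusted p = 0.0906). The call of Lyz2 ended without Control 1 or any single UV sample (adjusted p up to 0.119) and that of Csf1r without any single UV sample (up to 0.124). Of 8 neutrophil genes 0 were called on either adjustment (camera adjusted p = 0.514).

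Of 9 endothelial genes, which included Vwf (0.51, adjusted p = 0.0863), 0 were called over all genes and 5 were higher adjusted over the list alone (median 0.28; camera adjusted p = 0.00776; adjusted p = 0.565 with an estimated correlation). For 19 cell cycle genes 0 were called over all genes and 4 were higher adjusted over the list alone (median 0.12; camera adjusted p = 0.0165; adjusted p = 0.646 with an estimated correlation), a list call that ended without UV 2 (0.102). Among 20 cytokine and chemokine genes, with Cxcl9 at 1.08 (adjusted p = 0.0508), 0 were called on either adjustment (median 0.23; camera adjusted p = 0.0474; adjusted p = 0.646 with an estimated correlation). Of 17 immediate early genes 0 were called over all genes and 3 were lower adjusted over the list alone (median −0.24; camera adjusted p = 0.0474; adjusted p = 0.646 with an estimated correlation). The cytokine call ended without Control 1, Control 2, UV 1 or UV 2 (adjusted p up to 0.266) and the immediate early gene call without Control 1 or any single UV sample (up to 0.216). Without Control 3, 3 cytokine and 2 endothelial genes rose and 2 immediate early genes fell over all genes.

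The growth factor binding protein gene Igfbp3 (−1.74, SE 0.12, adjusted p = 0.00111) fell as the 1 of 8 senescence genes called over all genes, against 2 lower adjusted over the list alone (camera adjusted p = 0.211). Txnrd1 (−0.38) fell as the 1 of 20 antioxidant genes called, against 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.177). The call of Txnrd1 ended when any of the 6 samples was left out (adjusted p from 0.05 to 0.182), while 6 antioxidant genes rose without Control 3. Rgs5 (0.44) rose as the 1 of 8 smooth muscle and pericyte genes called, against 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.679). The call of Rgs5 ended with library size only (adjusted p = 0.0713) and without Control 1, Control 2 or any single UV sample (up to 0.162). None of 12 fibroblast genes (camera adjusted p = 0.277), 8 melanocyte genes (0.0523, with 8 of 8 values negative), 6 Schwann cell genes (0.363), 5 erythroid genes (0.386) or 17 interferon response genes (0.64) was called on either adjustment by edgeR. The 23 genes of the m6A machinery, Virma among them, had 0 calls on either adjustment (median 0.06; camera adjusted p = 0.311). The medians of the m6A machinery (−0.05) and of Schwann cells (0) left their positive side with library size only.

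Of 33 lists, camera called 17 (9 higher and 8 lower), camera with an estimated correlation called 0, and fry called 5. Camera with the preset correlation also called 15 lists when Control 1, Control 2 and UV 3 were set against the other samples. The number of its list calls therefore does not set the UV split apart. Fry called the lists of the p53 and DNA damage response and of sebocytes higher. It called those of T cells, Langerhans and dendritic cells and senescence (median −0.21) lower, the last of which camera did not call.

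**Figure D2:**
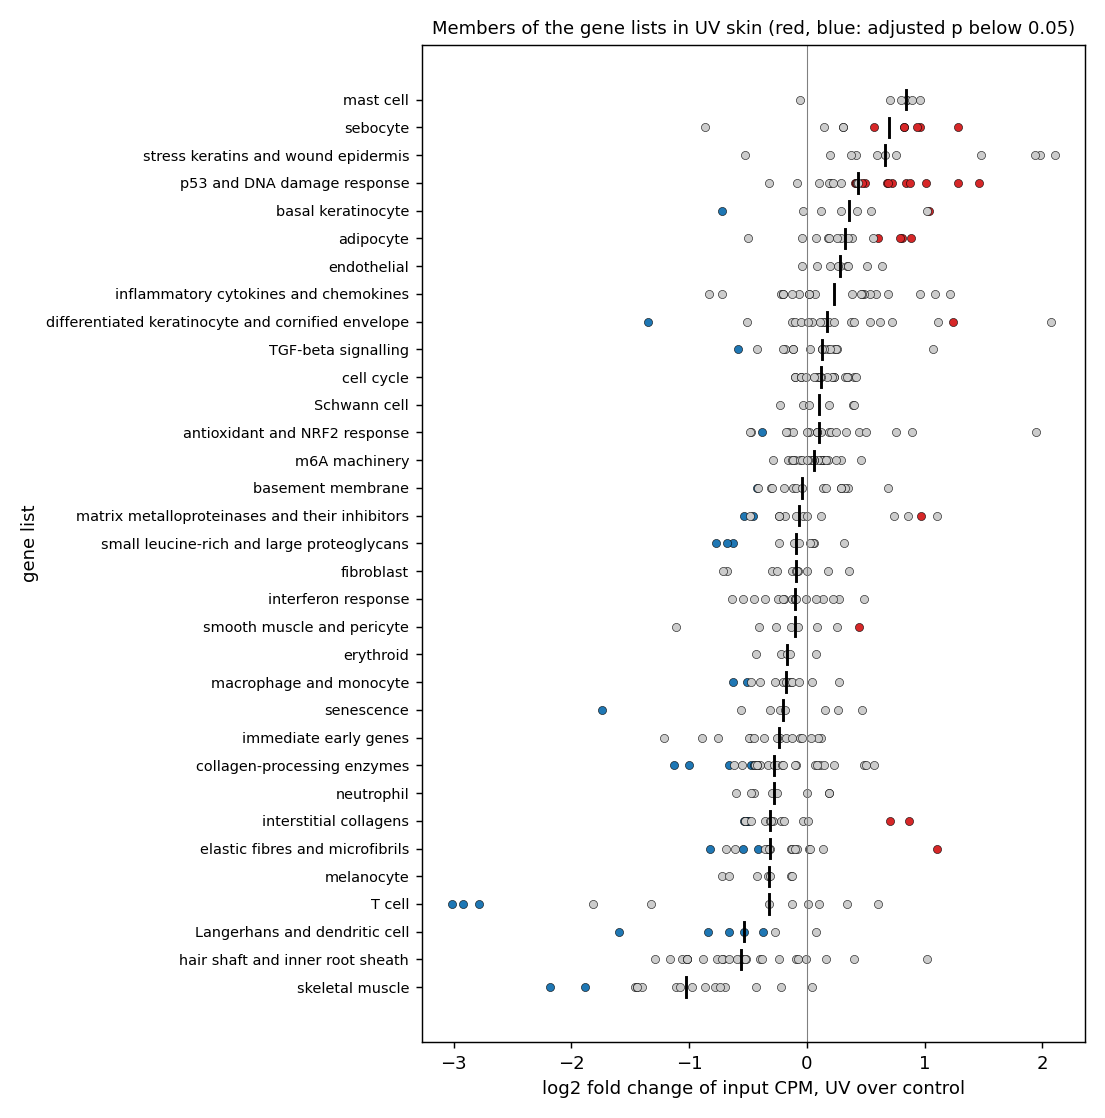
Log2 change of each member gene between UV and control input libraries for the gene lists, with genes at an adjusted p below 0.05 in red (higher) or blue (lower) and a black bar at each list median. The p53 list has its median at 0.43 and the skeletal muscle list at −1.03.

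The next question was which transcripts the m6A antibody enriched within each group. Transcripts of ribosomal protein genes, which carry little m6A, lay 0.43 below all genes in log2 IP over input (a difference of −0.434 ± 0.028, SD over 6 pairs, 83 genes), and between −0.48 and −0.40 in every pair. Among called genes with at least 5 CPM in the group's input, the most enriched in control skin were the pseudogene Gm13339 (2.51, SE 0.13, adjusted p = 3.71e-08), the mitochondrial tRNA gene mt-Te (2.40), the fucosyltransferase gene Fut1 (2.24), the lipid receptor gene S1pr5 (2.19) and the ribosome assembly gene Rrs1 (2.14). The most depleted were the small nucleolar RNA genes Snord38a (−5.99, SE 0.87, adjusted p = 8.6e-05), Snora24 (−5.79) and Snord14e (−5.61), with Gm22126 (−5.71) and Gm24119 (−5.36). The value of Snord38a in control was −4.28 without Control 2 and −6.80 without Control 1, so that without Control 2 it lay behind the other 4. In UV skin Gm13339 (2.98, SE 0.13, adjusted p = 3.03e-08), Gm24924 (2.52), Gm5844 (2.19), RP24-366L10.3 (2.18) and Fut1 (2.17) were the most enriched above the same limit. Snord14e (−5.53, SE 0.61, adjusted p = 9.15e-06), Snord38a (−5.05), Snora24 (−5.05), Gm24119 (−4.96) and Gm23287 (−4.75) were the most depleted in UV above that limit. Over 25022 genes, 6144 were enriched and 6451 depleted in control, and 6179 and 6092 in UV. With library size only the counts were 3850 enriched and 8836 depleted in control (30.3% against 48.8% enriched with TMM) and 4574 and 7460 in UV (38% against 50.4%).

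The interaction asked where m6A enrichment differed between UV and control skin once transcript abundance was taken into account. The genes called were Gm23153, Gm22031 and Gm12912, each named as one of the 3 calls and chosen after its values were seen. Gm23153, of no stated class (chromosome 1, 190482845 to 190483157), went from a log2 IP over input of −4.98 ± 0.31 to −2.84 ± 0.21, a change of 2.15 (SE 0.19, adjusted p = 0.00151, n = 3 per group) at 109.5 CPM in input. Gm22031, a small nuclear RNA gene (chromosome 15, 3603272 to 3603397), changed by 3.13 (SE 0.37, adjusted p = 0.019) at 2.34 CPM, and Gm12912, a pseudogene (chromosome 4, 75147609 to 75148989), by 2.16 (SE 0.29, adjusted p = 0.0403) at 2.07 CPM. The call of Gm23153 ended without UV 1 (adjusted p = 0.0533) or UV 3 (0.0511). The calls of Gm22031 and Gm12912 ended with limma-voom (0.0713) and when Control 1, Control 3 or any single UV sample was left out, with adjusted p up to 0.254 and 0.72.

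Of 25022 genes, 1109 had an unadjusted p below 0.05 (698 higher and 411 lower). The DESeq2 Wald test called 52, limma-voom 1, and leaving out samples gave 0 (without UV 1 or UV 3) to 7 (without Control 2). With the sample block 399 genes were called, 211 higher and 188 lower, the 3 above among them. They included the small RNA genes Rny3 (1.41) and Rnu1b1 (1.44), the histone gene H2ac4 (0.76), the signal recognition particle RNA gene Rn7s2 (−0.84) and the adhesion gene Epcam (−0.42), which were chosen after their values were seen. Among genes that met the naming rule except for a call, the smallest p belonged to Snord49a (2.00, adjusted p = 0.188), Hspa1l (1.02, 0.25), Actb-ps1 (1.41, 0.251), Snord17 (1.04, 0.274) and H2ac4 (0.76, 0.274) on the higher side. On the lower side these were Zbtb8a (−0.63, 0.251), Mfap1b (−0.44, 0.501), Phf23 (−0.35, 0.541), Ercc3 (−0.37, 0.576) and RP24-178J22.1 (−0.38, 0.586). Hspa1l and H2ac4 overlap other annotated genes and Actb-ps1 resembles Actb, so the source of their reads is uncertain.

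For the interaction, camera called 0 of 33 lists, as did camera with an estimated correlation and fry. The median change was −0.06 for the m6A machinery, 0.07 for interstitial collagens, 0.09 for collagen-processing genes and 0.11 for elastic fibre genes, the first of which turned positive (0.03) with library size only. With the sample block the differentiated keratinocyte list was called lower (median −0.13, camera adjusted p = 0.0261; adjusted p = 0.806 with an estimated correlation), with 0 of 20 genes higher and 2 lower over all genes and 7 lower adjusted over the list alone.

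IP abundance asked how the antibody-bound transcripts alone differed, without correction for the input. Of 22789 genes 570 were called, 330 higher and 240 lower in UV. The log2 changes in IP and input correlated across 22318 genes with r = 0.703, where genes are not independent replicates. Of the 1347 genes called in input and 567 called in IP among these, 407 were called in both, with the same sign in 407 of 407. IP and input came from the same samples and share their departures, so this overlap is no independent measure of a UV effect. In the IP libraries Virma changed by 0.05 (adjusted p = 0.763) and Mfap4 by −0.34 (adjusted p = 0.421). The number of calls was 67 without Control 1, 370 without Control 2, 1248 without Control 3, 79 without UV 1, 89 without UV 2 and 237 without UV 3.

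The deposited table held 24969 peaks called in UV skin in 11564 genes and 18020 called in control skin in 9408 genes, with median lengths of 240 and 239 bp. Of these, 59.3% of UV peaks overlapped a control peak and 85.2% of control peaks overlapped a UV peak. The midpoint lay in an exon for 82.3% and 83.3% of them, and 55.1% and 55.2% overlapped the last exon of their gene.

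Peak-level change between UV and control was tested for peaks of Mfap4, Virma and the collagens and for all others. The Mfap4 peak called in UV (chromosome 11, 61488392 to 61488780, exon) went from a log2 IP over input of −0.79 ± 0.36 to 0.23 ± 0.10, a change of 0.98 (SE 0.28, adjusted p = 0.51, n = 3 per group) that was called with the sample block (1.01, SE 0.24, adjusted p = 0.0223). The Mfap4 peak called in control (61488661 to 61488780), which lies within it, changed by 0.39 (adjusted p = 0.812; with the sample block 0.39, adjusted p = 0.643). A peak near the end of Col1a1 (chromosome 11, 94952503 to 94952832) went from −0.88 ± 0.06 to −0.06 ± 0.10, a change of 0.82 (adjusted p = 0.511; with the sample block 0.82, adjusted p = 3.67e-06). The Col1a1 peak at 94951605 to 94951724 changed by 0.42 (adjusted p = 0.569; with the sample block adjusted p = 0.0116). The peak called in UV that contains it (94951545 to 94951904) changed by 0.11 (adjusted p = 0.918; with the sample block 0.12, adjusted p = 0.543). The change was 0.70 for the Col1a2 peak at 4540528 to 4541066 on chromosome 6 (adjusted p = 0.51; with the sample block 0.71, adjusted p = 0.000487). Another pair of Col1a2 peaks within it, called in control, changed by 0.69 and 0.70 (with the sample block adjusted p = 0.00142 and 0.017). Of 55 peaks in 13 collagen genes, edgeR called 0, 8 had an unadjusted p below 0.05, and 5 were called with the sample block, with 5 of 5 higher. These 5 are the Col1a1 and Col1a2 peaks called above. Those of Col1a2 overlap and share reads, so the 5 are not separate results. The 55 also count a place once for each arm that called it. Over the whole gene, the interaction with the sample block was 0.10 for Col1a1 (adjusted p = 0.735) and 0.12 for Col1a2 (adjusted p = 0.642), neither called. The Col1a1 peak at 94952503 had 6236 input reads in control and 2951 in UV, so fewer input reads went with its higher ratio. The longest Virma peak called in UV (chromosome 4, 11507965 to 11513083) changed by −0.37 (adjusted p = 0.555; with the sample block −0.38, adjusted p = 0.0655).

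Over all 42989 peaks edgeR called 0 without the sample block, with 3651 at an unadjusted p below 0.05 (2325 higher and 1326 lower). The share of higher peaks, 63.7% here, depended on the setting. It was 70.9% without UV 3, 70.5% without UV 1, 68.7% without UV 2, 66.9% without Control 3 and 64.6% with filterByExpr. It was 55.1% with DESeq2 size factors, 52.5% in control-called peaks only and 51.2% without Control 1. It fell to 47.8% with the sample block, 43.8% without Control 2 and 39.2% in UV-called peaks only. The arm-only values come from refits with TMM factors computed on the peaks of that arm alone. In the joint fit, 79.7% of UV-called and 33.5% of control-called peaks at an unadjusted p below 0.05 were higher. Fits with limma-voom and DESeq2 size factors, which leave out the pairing of IP and input as well, also gave 0. Leaving out Control 2 gave 4. With the sample block 516 peaks at 374 loci were called, 185 higher and 331 lower. The higher peaks with the smallest p lay in Mark3 (1.78), Actb (0.88), Dynll1 (0.91 and 0.90 for the peaks of each arm), Cox6b1 (1.10), Klhdc2 (1.63), Hoxc8 (1.58), Rpl11 (1.72) and Slc3a2 (4.53, with 5 input reads in UV), and in Naip2, where 0 UV input reads allow no fold. The lower ones lay in Eif3b (−0.69), Phf6 (−0.82), Hic1 (−0.90), Cecr2 (−0.97), Zbtb8a (−0.65), Hnrnpk (−0.56), Clcn6 (−2.74), Ercc3 (−0.50, the same interval in each arm) and Polr3d (−0.65). Each had an adjusted p of 0.509 and was called with the sample block.

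**Figure D3:**
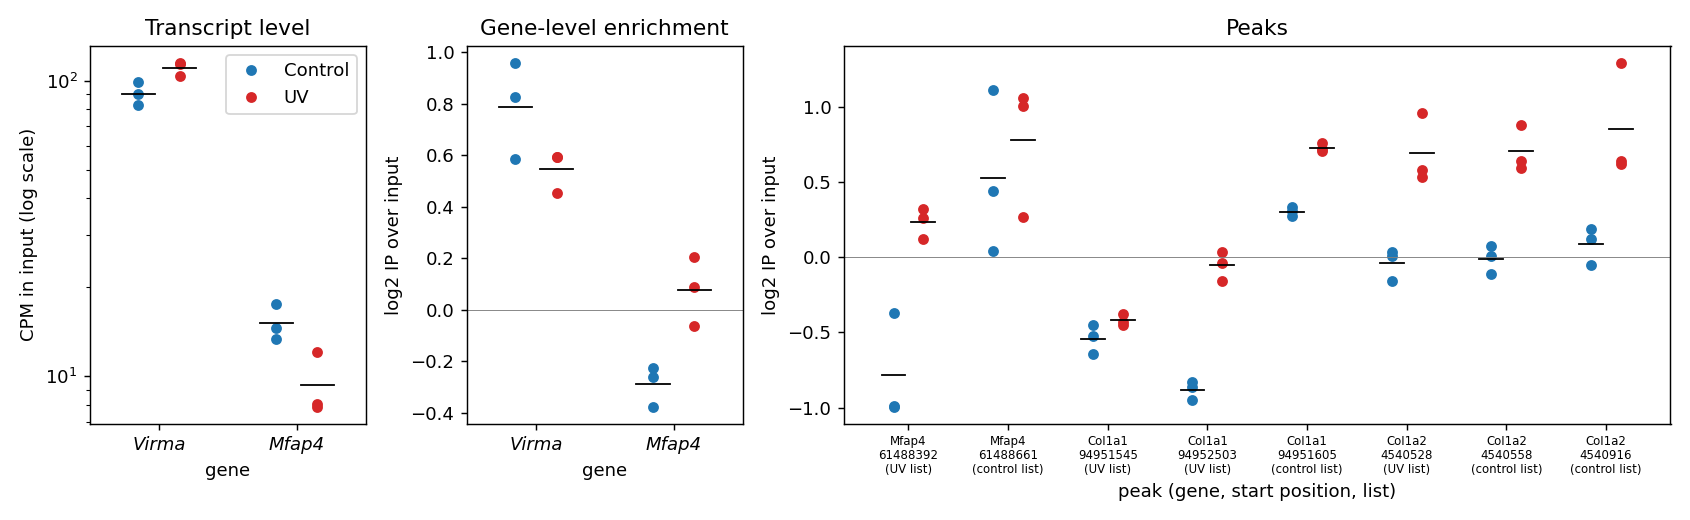
Per sample, input CPM of Virma and Mfap4 on a log axis, their log2 IP over input, and log2 IP over input of the Mfap4, Col1a1 and Col1a2 peaks, with control in blue, UV in red and a line at each mean. Mfap4 lies lower in UV input and higher in UV log2 IP over input.

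In the authors' deposited table, 45 peaks had an FDR below 0.05, 43 higher and 2 lower in UV. The Mfap4 peak called in UV had a log2 change of 1.01 with p = 0.00944 and FDR = 0.582 in the authors' deposited table. The peak with the smallest p in the authors' deposited table lay in the ribosomal RNA-like locus Rn18s-rs5 (2.12, FDR = 1.44e-10), followed by Fam163b (4.44, FDR = 8.54e-08, with 7 input reads in UV). Of the 45 peaks called in the authors' deposited table, 27 had fewer than 50 input reads in an arm, 40 had an unadjusted p below 0.05 in edgeR, and 29 were called with the sample block. The log2 values of edgeR and of the authors' deposited table correlated with r = 0.993 across peaks, leaving out 202 without a finite value there. Both came from the same libraries, so this correlation is no separate check.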

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

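The tests on small structural RNAs and the choice of that gene class were made after the result had been seen, whereas the interaction test and the other splits of the samples were planned.

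The effect of the antibody on a transcript, IP over input, differed between UV and control skin by a test of that difference for Gm23153 (log2 change 2.15, SE 0.19, adjusted p = 0.00151), Gm22031 (3.13, SE 0.37, adjusted p = 0.019) and Gm12912 (2.16, SE 0.29, adjusted p = 0.0403). All 3 UV samples lay above all 3 control samples for each of them. Gm23153 rose from a strongly depleted level in control (−4.98 ± 0.31) to a less depleted one in UV (−2.84 ± 0.21), so that it was depleted in both groups. Gm22031 and Gm12912 had 2.34 and 2.07 CPM in input. The split into UV and control gave these 3 calls, and the highest count among the other splits was 0; 10 splits cannot give a share under 0.05. With the sample block the counts were 399 and 0.

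Among the 211 genes called higher with the sample block, 60 (28.4%) were small structural RNAs, against 679 of 25022 genes tested (2.71%; Fisher's exact test, two-sided, p = 5.58e-44, across genes that are not independent). They included 28 of 167 small nuclear RNA genes and 22 of 216 small nucleolar RNA genes, but 2 of 265 microRNA genes. Noise of genes with few input reads is argued against. At 10 CPM or more in input, small RNAs still made up 30.6% of the higher calls (34 of 111) against 1.06% of genes tested. Noise from few IP reads stays open, since the limit was set on input alone. Snora24, for one, had 22.3 CPM in control input but a log2 IP over input of −5.50 there. A difference in the recovery of short RNAs between IP and input preparations stays open and may explain part of the pattern, since protein-coding genes and pseudogenes of at most 400 bp also moved up, with a median of 0.214 (95% bootstrap interval 0.155 to 0.293, 470 genes, median 0.794 CPM), against −0.014 (−0.017 to −0.011) for those over 1000 bp. The share of reads in Rn18s and Rn45s was 0.270% to 0.307% in the UV input libraries and 0.325% to 0.404% in the control ones, while in IP it was 0.111% to 0.118% in UV, within the 0.0988% to 0.147% of control. Input levels moved too: Snord49a changed by −1.93 in input and by 2.00 in the interaction. Input CPM was lower in UV for Snora24 (22.3 to 14.3), Snord38a (15.6 to 8.86) and Snord14e (18.7 to 15.2), the small nucleolar RNA genes named in both groups. Whether lower input or more IP raised the ratio over the class was not tested. A change in the modification of small RNAs with UV, which the design names, was not tested apart from this and stays open too.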

How the results depend on the processing

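Dividing counts by 2, the added peak settings and the blocks in the list tests were chosen after seeing the data. Single genes named in the expression comparison kept their side of the threshold in 686 comparisons with an alternative, lost the call in 79 and gained one in 8; with single samples left out the numbers were 310, 204 and 2, and 0 reversed.

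Counts of calls moved as follows. Requiring a 2-fold change gave 512 genes for expression, 267 for IP abundance, 4738 for enrichment in control and 4355 in UV, by construction. The DESeq2 Wald test gave 2620 for expression, 1368 for IP abundance and 52 for the interaction. Without a low-count filter these were 2152, 1426 and 22, over more genes tested. For the interaction, limma-voom gave 1 and library size only 5. Camera with an estimated correlation called 0 lists and fry 5. In the authors' deposited table an FDR below 0.005 left 11 peaks. Overlap of 50% of the shorter peak left 57.4% of UV and 82.9% of control peaks shared. Apart from thresholds, filters and overlaps, the cause was not tested.

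Blocks acted in different directions. The replicate number, which does not pair control with UV samples, gave 713 genes for expression, 247 for IP abundance and 18 lists. The sample shared by IP and input gave 399 genes for the interaction, 516 peaks and 1 list for the interaction, where the pairing correlations show shared departures of IP and input.

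With library size only, the enrichment of Mfap4 in UV reversed to −0.080 (adjusted p = 0.785), a change of scale that moved all genes down.

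Leaving out single samples gave 219 to 2100 genes for expression, 67 to 1248 for IP abundance, 10105 to 12172 for enrichment in control, 9232 to 12931 for enrichment in UV, 0 to 7 for the interaction, 10 to 16 lists, 0 lists for the interaction and 0 to 4 peaks. The difference for ribosomal protein genes stayed between −0.441 and −0.425. Fewer samples lower the power of a test, but leaving out Control 3 raised the count for expression and IP abundance, and the cause was not tested.

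The interaction calls of Gm22031 and Gm12912 ended in 6 alternatives each and that of Gm23153 in 2, and the cause was not tested.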

Other observations

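The tests that weigh the T cell and the clock patterns below, and the lists they use, were chosen after the results had been seen. The p-values of lists written then are therefore no independent support for these patterns. The splits of the samples were planned.

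Transcripts of the skin's gamma delta T cells were lower in UV input. The receptor genes Trgc1 (log2 change −3.67, SE 0.31, adjusted p = 0.00229), Trdv4 (−3.26, SE 0.42, adjusted p = 0.00696) and Trdc (−2.92, SE 0.47, adjusted p = 0.0142) fell, with Cd3g (−2.79) and Cd3e (−3.01). Trgv5, whose variable segment marks dendritic epidermal T cells, had 22, 13 and 16 reads in the control input libraries (0.378 ± 0.114 CPM) and 0 reads in the UV ones, which with a floor of 3 counts per library makes it at least 5.9-fold lower. Of 8 genes 6 fell over all genes and 7 adjusted over the list alone (median −2.97, or −2.86 with Trgv5 at its bound; camera adjusted p = 6.61e-10 over 5 lists; adjusted p = 0.0616 with an estimated correlation). Cd3e, Cd3g, Cd3d and Trdc are also in the T cell list, and Cd3e, Cd3g, Cd3d and Cd247 are not particular to gamma delta T cells. The call of Trdc ended without UV 2 (adjusted p = 0.0663) or UV 3 (0.065), and that of Trgv5 without Control 1 (0.0573) or UV 3 (0.0517). Genes of MHC class II presentation fell as well, 5 of 7 over all genes, with Ciita, their transcriptional activator, at −0.62 (adjusted p = 0.0257) and the list at a median of −0.62 (camera adjusted p = 0.00016; adjusted p = 0.0616 with an estimated correlation). Cd74, H2-Aa, H2-Ab1 and H2-Eb1 are also in the Langerhans and dendritic cell list, so these values are not separate evidence. The calls of Ciita (adjusted p up to 0.103), H2-Aa (up to 0.0954) and H2-Ab1 (up to 0.0841) ended without Control 1 or any single UV sample, and that of H2-Eb1 (up to 0.13) without any of these or Control 2, which left 1 of the 5 without Control 1 or any single UV sample.

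Less epidermis in the UV samples is argued against, since basal keratinocyte genes had a median of 0.356 (median absolute deviation 0.462, 8 genes), far from the fall of the gamma delta genes. The alpha beta T cell genes did not fall as a list. Their median was 0.289 (−0.124 to 0.504 over 5 genes, 0 called by edgeR, camera adjusted p = 0.19). Some had few reads, such as Cd8a with 0 to 20 per input library. They cannot show whether the share of all T cells fell, since Cd3g (−2.79) and Cd3e (−3.01), also in the T cell list, were lower. A fault of the input libraries alone is argued against by the IP libraries, where the gamma delta genes had a median of −2.933 (7 genes). A loss of dendritic epidermal T cells and Langerhans cells from UV-exposed epidermis may underlie these values, and a difference between the samples that was there before exposure cannot be excluded; cell numbers were not analysed here.

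Genes of the circadian clock moved in opposite directions. In the list named clock output, Dbp (1.89), Ciart (1.55, SE 0.12, adjusted p = 0.00158), Per1 (1.11, adjusted p = 0.0101), Per2 (1.00, adjusted p = 0.0172) and Per3 (0.90, adjusted p = 0.00966) rose. In the list named clock activators, Arntl (−0.60, SE 0.09, adjusted p = 0.00972) and Npas2 (−1.41, SE 0.21, adjusted p = 0.012) fell, while Clock rose (0.56, adjusted p = 0.0373). Both names are loose. The output list also holds repressor genes of the clock loop, such as Per1 and Per2, and the activator list holds the repressor gene Nfil3. Of 10 output genes 8 rose over all genes and 9 adjusted over the list alone (median 0.85; camera adjusted p = 1.91e-08; adjusted p = 0.0616 with an estimated correlation). The 5 activator genes, which went both ways, were not called as a list (camera adjusted p = 0.138). In the IP libraries 7 output genes rose. With single samples left out, the calls ended for Per2 (adjusted p up to 0.0776) and Nr1d1 (up to 0.0874) without Control 1, UV 1 or UV 3, for Arntl without UV 1 or UV 3 (up to 0.0582), for Npas2 without Control 1, UV 2 or UV 3 (up to 0.0599) and for Clock without Control 1 or any single UV sample (up to 0.149).

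UV and control skin collected at different times of day could give the same 8 higher output genes with lower Arntl and Npas2. Because the labels give no time of collection, that explanation and an effect of UV on the clock cannot be told apart.

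Other splits of the same samples into 3 against 3 were fitted as well, and 10 splits cannot give a share under 0.05. The real split gave 1404 genes for expression and the highest of the others 1. The pairs of values were 570 and 0 for IP abundance, 17 and 15 for the lists in expression, 0 and 2 for the lists in the interaction, 0 and 0 for peaks, and 516 and 2 for peaks with the sample block. For IP against input the values were 12595 and 0 within control and 12271 and 0 within UV. There the IP and input of a sample are paired, and 4 of the 10 splits, the real one included, part all 3 pairs; the rest part 1 pair.

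In the authors' deposited table, 2062 of 2367 peaks at p below 0.05 (87.1%) were higher in UV. At loci called in both arms the share was 84.8% for peaks called in UV and 77.7% for peaks called in control in the authors' deposited table, whereas edgeR with TMM gave 51.1% and 42.9% for its own peaks at p below 0.05. Among peaks called at these loci with the sample block, at the stricter adjusted p, 26.9% of 171 called in UV and 22.5% of 191 called in control were higher. At loci called in 1 arm only, 99.5% and 97.6% of peaks called in UV were higher, in the authors' deposited table and edgeR in turn. For peaks called in control the values were 2.91% and 2.05%. A call in 1 arm only selects on the same libraries, so these directions were largely set by the selection and favour neither test.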
